A study of Bacillus subtilis with 3 samples.

How the data were processed

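RNA immunoprecipitation followed by sequencing was done in Bacillus subtilis 9407 with His-tagged polynucleotide phosphorylase (PNPase) and with PNPase D493A, a catalytically inactive form. The D493A group had 2 samples and the PNPase group had 1 sample. Per the labels, the cells lacked their own pnpA gene and carried a plasmid copy induced with 0.1 mM IPTG. Per the series design, RNA bound by an anti-His antibody was sequenced alongside input RNA and an IgG control, with a library that keeps the strand.

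Trimmomatic 0.36, STAR 2.5.3a, bedtools 2.25.0 and deepTools 2.4.1 are named in the submitters' processing notes, without their roles. The peak caller, its threshold and the genome build are not given in the sources used here. The authors deposited 1 peak list per protein. The D493A list is taken here to cover both D493A samples, from its name alone. Whether it does, and how the samples were combined, is not given in the sources used here. Each peak carries a fold enrichment, which is the authors' ratio, and the authors' p-value and false discovery rate. Their normalisation is not given in the sources used here, and neither is the sequencing depth of any sample. The authors' folds are therefore not compared between lists. They serve to describe, rank, filter or split peaks within 1 list, and 1 check of the peak limit sets step units, not folds, side by side. Depth is unknown for every sample, so a longer list can reflect more reads as well as more bound RNA.

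Coordinates are those of the authors' lists, on the contigs of a draft genome, numbered here as in the sequence names. The deposited starts count from 0 and were raised by 1. The deposited length column was 1 bp too long for all 3880 D493A peaks and all 830 PNPase peaks, so widths were computed from start and end. Features were sorted into coding sequences, RNA genes and features named by coordinates alone. The last 2 classes are called untranslated here. The kind of each RNA gene is not given in the lists, and near-identical copies of such genes can share reads, so values for single RNA genes are uncertain.

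Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. Peaks overlapped when they shared at least 1 bp on the same strand. Chance overlap came from 1000 random rotations of the PNPase list along the joined contigs, with a one-sided permutation p whose smallest possible value is 0.001. Shares have exact Clopper-Pearson 95% intervals, which cover counting error only. Classes and contigs were compared with Fisher's exact test, two-sided, and Benjamini-Hochberg adjustment. Differences of medians and midpoints used 100000 permutation resamples, two-sided, with a smallest possible p of 1e-05. Clustering was tested with 1000 shuffles of the PNPase calls over the D493A features, in windows of 25 neighbouring features, and in pairs on 1 strand at most 50 bp apart. With 1 PNPase sample and 1 list per protein, no test across replicates could be made. Every p-value here describes the lists and not the spread between cultures.

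Several tests departed from the plan fixed before the data were examined. The planned background for shared genes, all genes in either list, held no gene without a peak. Locus tag numbers that are multiples of 5 were therefore used as background, 4255 in all. Only 3838 tags occur in either list, and the rest were presumed from the numbering. The planned comparison of peak position between lists was void because nearly every D493A peak on a coding sequence had a length of whole codons, as a complete coding sequence has. Such D493A peaks were therefore taken as gene extents, which no annotation could check here, and PNPase peaks covering part of a gene were tested for the end they reached. RNA genes as a whole stood in for ribosomal and transfer RNA genes. None of the 3838 locus tags matched the reference table of the species, so the 16 gene lists fixed beforehand, with 505 entries, were not analysed here. The rule for named genes took the highest peaks of each list by fold, the best genes of both lists and the highest peaks of the PNPase list alone. As no names could be paired with the tags, only the 2 highest of each list are named by tag.

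Alternatives chosen before the data were examined were a 50% overlap of the shorter peak, strand ignored, the upper part of each list by fold, a D493A list shortened to 830 peaks by fold, RNA genes left out, the widest 10% of peaks left out, genes longer than 2 times the median peak width, and the 3' end of the peak in place of its midpoint. Leaving out contig 11, shortening the D493A list by p, and splitting by strand were added after seeing the data. So were the split of D493A folds and p-values by PNPase peak, and the tests of contigs, windows and neighbours. The tests of overlap, gene ends, midpoints, classes, windows, neighbours, medians, fold steps and common odds ratios were checked on simulated data. The rotation test called 0 of 20 random lists at 0.05, and 830 of 830 planted overlaps were recovered. The random lists were placed anywhere on the contigs, so they do not check the test for peaks that lie on annotated features. A planted lean to the 5' gene end was found in 100 of 100 simulations, and a lean along the contig alone was mistaken for one in 6 of 100.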

Results

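RNA bound to PNPase and to its catalytically inactive form D493A was mapped by immunoprecipitation in B. subtilis 9407. PNPase is an exoribonuclease that degrades RNA from the 3' end. The D493A group had 2 samples and the PNPase group 1, with 1 list of peaks per protein. Depth was unknown, and no value had a replicate error.

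The first question was how much RNA each protein held. The D493A list had 3880 peaks on 3868 annotated features, and the PNPase list had 830 peaks on 781 features, so the D493A list was 4.67 times as long. D493A peaks covered 42.9% of both strands of the contigs and PNPase peaks 5.37%. The lists were even over the strands, with 1980 D493A peaks on the plus strand and 1900 on the minus strand, against 417 and 413 for PNPase. D493A peaks were also wider, with a median of 777 bp (95% interval 765 to 798) against 419 bp (389 to 444). Of 3797 D493A peaks on coding sequences, 3738 had a length divisible by 3 bp (98.4%, 98.0 to 98.8), as 33.3% of lengths are by chance. Of 777 such PNPase peaks, 426 had (54.8%, 51.2 to 58.4).

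The authors' fold enrichment had a median of 94.05 in the D493A list (88.9 to 97.8) and 12 in the PNPase list (11.6 to 12.6). These scores came from separately called lists and are not on 1 scale. The lower quartile of PNPase folds was 9.69, also their commonest value, at 106 peaks. It was the lowest fold among PNPase peaks whose p matched a binomial test against 1 input read. Many PNPase peaks thus lay at or near the lowest fold such peaks had. A missing PNPase peak therefore does not show that an RNA was not bound. The highest D493A peak lay on the coding sequence CWT11_RS13230 (contig 16, 605633 to 606394, minus strand) at a fold of 1400, followed by CWT11_RS17235 (contig 16, 1423236 to 1424111, minus strand) at 1390. The highest PNPase peak lay on the RNA gene CWT11_RS00885 (contig 12, 234 to 310, plus strand, 77 bp) at 74.4. The coding sequence CWT11_RS00640 (contig 11, 29523 to 31601, plus strand) was next at 71.7.

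The second question was whether both forms held the same RNAs. Nearly all PNPase peaks overlapped a D493A peak. Of 830 PNPase peaks, 823 (99.2%) overlapped a D493A peak on the same strand, against a mean of 52.5% when the list was rotated (one-sided permutation p = 0.001, the smallest the rotations can give). Rotation also moves peaks off annotated features, and 3830 of the 4255 locus tags used as background (90.0%) had a D493A peak, so 52.5% understates the share expected for peaks on genes. The highest rotated overlap was 75.2%, below that 90.0%. A list of randomly chosen genes would thus be likely to give the same p. In the other direction, 792 of 3880 D493A peaks (20.4%) overlapped a PNPase peak. By locus tag, 755 of 763 genes with a PNPase peak also had a D493A peak (98.95%), an odds ratio of 12.8 (6.33 to 25.9, Fisher's exact p = 1.69e-27). Every tag seen had a peak in at least 1 list, so the genes with a peak in neither were all presumed from the numbering. Without those presumed genes this odds ratio has no support. The size of this odds ratio depended on the lists. It was 1.92 with the widest 10% of peaks left out, 2.43 with the D493A list shortened to 830 peaks by fold and 3.51 in the upper part of each list. Without RNA genes it was 111 (15.6 to 795), with only 1 gene in the PNPase list alone. All settings used the same 4255 tags, so genes that a setting took out counted as genes without a peak. The overlap was 35.3% with the D493A list shortened to 830 peaks by fold and 64.3% with it shortened by p. Rotation gave means of 14.9% and 12.5% (permutation p = 0.001 for each), with the same limit for peaks on genes.

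Only 8 features had a PNPase peak and no D493A peak. Of these, 7 were RNA genes, and 1 was a coding sequence with a peak of 153 bp on contig 15 (664904 to 665056, fold 15.5). That peak did overlap a D493A peak on the same strand, assigned to another feature, as all 795 PNPase peaks outside RNA genes overlapped one. The longest of the RNA genes covered 1550 bp of contig 9 (9 to 1558, fold 3.95), and the one with the highest fold lay on contig 1 (1 to 62, fold 19.2). These 8 were looked at after their values were seen.

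Features with a PNPase peak had stronger evidence in the D493A list. The share with a PNPase peak was 60.8% (57.3 to 64.3) in the quintile of D493A features with the smallest p and fell over the next quintiles to 23.4%, 10.6% and 4.26%, then to 0.904% (0.364 to 1.85) in the quintile with the largest p. The gradient was shallower by the authors' fold, from 9.82% in the lowest quintile to 30.4% in the highest. Median D493A fold was 133 for features with a PNPase peak and 84.5 for those without, a log2 difference of 0.65 (permutation p = 1e-05, the smallest the resamples can give). The call was lost in the upper part of each list by fold (0.11, permutation p = 0.106) and with the D493A list shortened by fold (-0.0073, permutation p = 0.889). The difference turned to -0.43 among the 830 D493A peaks of smallest p (permutation p = 1e-05, again the smallest).

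**Figure D1:**
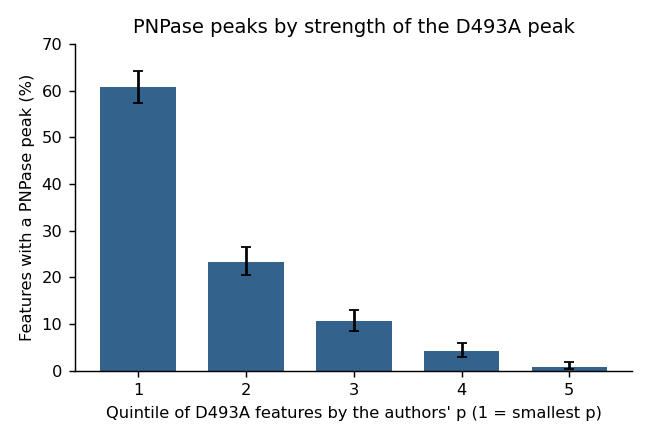
Bars show the percentage of D493A features that also had a PNPase peak, by quintile of the authors' p for the D493A peak, with exact 95% intervals. The share fell from 60.8% in the quintile with the smallest p to 0.904% in the quintile with the largest.

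The third question was which kinds of RNA were held. Untranslated features took a larger part of the PNPase list, with 53 of 830 peaks (6.39%) against 83 of 3880 D493A peaks (2.14%). The odds ratio was 3.12 (adjusted p = 9.13e-09, Fisher's exact test). It was 2.03 (1.26 to 3.26) with the D493A list shortened to 830 peaks by p. It was 6.33 in the upper part of each list by fold and 14.1 with the D493A list shortened by fold. Median D493A folds were 22 for RNA genes and 36.05 for coordinate-named features, against 95.6 for coding sequences. Selection by D493A fold thus takes untranslated features out, and the values by fold, here and for each class below, add no support. RNA genes accounted for 35 PNPase peaks (4.22%) and 45 D493A peaks (1.16%), an odds ratio of 3.75 (2.4 to 5.87, adjusted p = 5.70e-08, Fisher's exact test). For RNA genes it was 12.5 in the upper part of each list by fold and 12.1 with the D493A list shortened by fold. Features named by coordinates alone accounted for 18 (2.17%) and 38 (0.979%), an odds ratio of 2.24 (1.27 to 3.95, adjusted p = 0.00735, Fisher's exact test). Against a D493A list shortened to 830 peaks by p, the odds ratio for this last class was 1.20 (0.603 to 2.41), and its call was lost. Shortened by fold instead, it was 18.4 (2.45 to 138, adjusted p = 7.02e-05, Fisher's exact test), and with the upper part of each list by fold it was 2.35 (0.704 to 7.84), where the call was again lost. Most RNA genes were short, with 40 of 45 D493A peaks and 31 of 35 PNPase peaks between 62 and 93 bp.

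Counted by feature, untranslated RNAs with a D493A peak were also the ones that most often had a PNPase peak. Of 45 RNA genes with a D493A peak, 28 had a PNPase peak (62.2%, 46.5 to 76.2), as had 18 of 38 coordinate-named features (47.4%, 31.0 to 64.2). Of 3785 coding sequences with a D493A peak, 727 had one (19.2%). The odds ratio of untranslated against coding features was 5.23 (3.37 to 8.12, Fisher's exact p = 5.66e-13). As 773 of 781 features with a PNPase peak also had a D493A peak, this restates the class shares above. It is no separate support for them. At the start of contig 16 (6 to 1836), 17 RNA genes of 73 to 93 bp had a peak in at least 1 list. Of these, 16 had a D493A peak, 15 a PNPase peak and 14 both, and genes there with a peak in neither list were not counted. These 14 are among the 28 RNA genes with both peaks, so the interval around 5.23 is likely too narrow and its p too small.

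**Figure D2:**
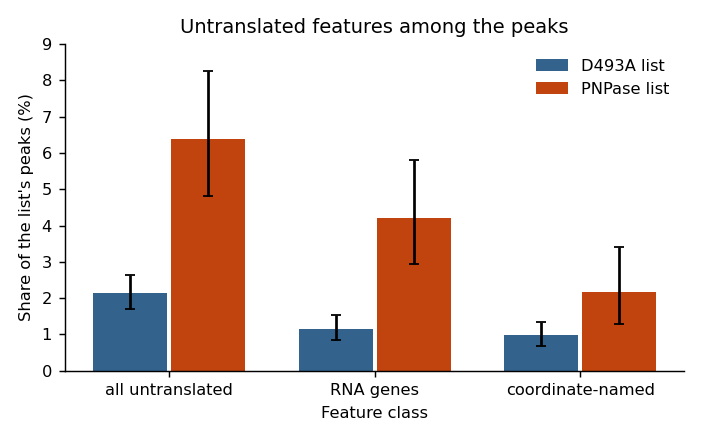
Bars show the percentage of each list's peaks on untranslated features, in all and by class, with exact 95% intervals. Untranslated features made up 2.14% of the D493A list and 6.39% of the PNPase list.

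Genes held by PNPase were concentrated in parts of the genome, and contig 11 stood out. There, 48 of 77 D493A features (62.3%, 50.6 to 73.1) had a PNPase peak, against 725 of 3791 elsewhere (19.1%), an odds ratio of 7.0 (4.38 to 11.2, adjusted p = 2.19e-15, Fisher's exact test over 8 contigs). Much of contig 11 also had small D493A p-values. In the quintile of smallest p, 45 of 54 contig 11 features had a PNPase peak (83.3%) against 59.1% elsewhere, but 721 of the 773 features in it have a p listed as 0, so their strength is not matched. Over all quintiles the common odds ratio, with that limit, was 2.52 (1.4 to 4.51). In the next quintile 3 of 11 had one (27.3% against 23.3%), and in the last ones 0 of 8, 0 of 1 and 0 of 3. Of the other contigs, contig 7 was also higher (33.9%, adjusted p = 0.0336), and contigs 13 (15.2%, adjusted p = 0.0336) and 16 (18.5%, adjusted p = 0.0352) were lower, by Fisher's exact test. Fisher's exact test takes features as independent, but close neighbours on 1 strand often both had a PNPase peak. Where a feature had one, its neighbour at most 50 bp away had one in 57.6% of cases, against 773 of 3868 features in all. The p-values by contig are therefore likely too small and the intervals too narrow, for contig 11 as well. The calls for contigs 7, 13 and 16, near the threshold of 0.05, cannot be relied on. On contig 11 the PNPase peaks fell mainly between 9886 and 57318, where 45 of 65 features had one, all 65 on the plus strand. With the D493A list shortened to 830 peaks by fold the share on contig 11 was 45.8% and its call was lost (adjusted p = 0.337, Fisher's exact test).

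**Figure D3:**
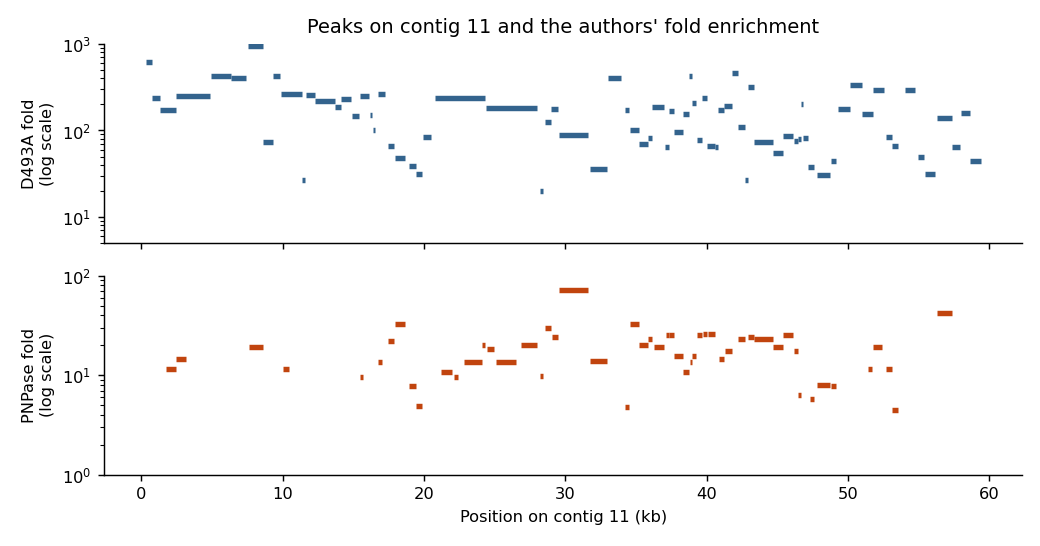
Each horizontal line is a peak on contig 11, drawn from its start to its end in kb, at the authors' fold on a log scale, for D493A above and PNPase below. The PNPase peaks lie mainly between 9886 and 57318 bp, with the highest at a fold of 71.7.

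The last question was where along genes PNPase was found. Of 771 PNPase peaks placed in 722 coding sequences, 218 (28.3%, 25.1 to 31.6) covered the whole gene and 158 (20.5%) lay inside it without reaching an end. Among the others, 231 reached only the 5' end and 164 only the 3' end, so that 58.5% (53.4 to 63.4) lay at the 5' end (exact binomial p = 0.000875). The median midpoint of the 553 peaks covering part of a gene was at 0.471 of the gene (0.454 to 0.487, permutation p = 0.0034 for the mean offset from the middle), at 0.519 on the plus strand and 0.454 on the minus strand. In genes longer than 2 times the median peak width the midpoint's call was lost (permutation p = 0.0539). The strands differed in this respect (Fisher's exact p = 4.84e-08). On the minus strand 153 peaks reached the 5' end and 63 the 3' end (70.8%), whereas on the plus strand the numbers were 78 and 101 (43.6%, exact binomial p = 0.0998). Balanced over the strands, the ratio of 5' to 3' peaks was 1.37 (1.11 to 1.69). In genes of the D493A list shortened to 830 peaks by fold, 54.1% lay at the 5' end, the call was lost (exact binomial p = 0.322), and the balanced ratio was 1.15 (0.846 to 1.56).

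**Figure D4:**
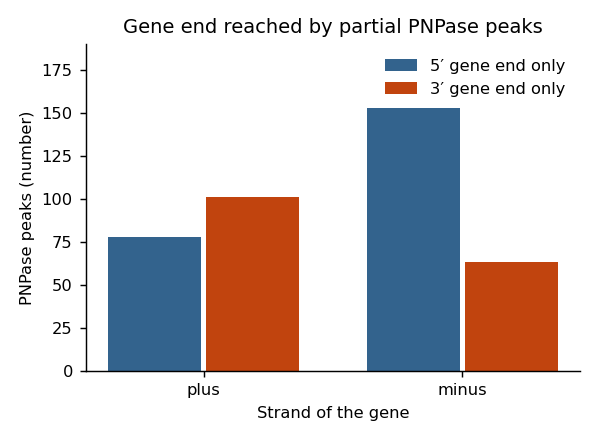
Bars show the number of PNPase peaks that reached only the 5' or only the 3' end of a coding sequence, for genes on each strand. On the minus strand 153 reached the 5' end and 63 the 3' end, and on the plus strand 78 and 101.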

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

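All tests of explanations in this part were chosen after the results were seen, except those of list length and of stronger D493A evidence for untranslated features as a whole, which were written down before their outcomes.

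The PNPase list held a larger part of untranslated features than the D493A list, with odds ratios of 3.12 for all of them, 3.75 for RNA genes and 2.24 for coordinate-named features. A difference between the groups brought these up. List length as the cause is argued against for the class as a whole, since the D493A list shortened by p held 3.25% untranslated peaks against 6.39%, and for RNA genes, at 1.45% against 4.22%. For coordinate-named features list length cannot be told apart, since their share was 1.81% (1.01 to 2.96) in the list shortened by p, against 2.17% (1.29 to 3.41). Their share of 0.120% in the list shortened by fold cannot decide this, because their D493A folds were lower than those of coding sequences. Stronger D493A evidence is argued against by a common odds ratio within D493A p classes of 5.21 for untranslated features. Split afterwards by class and by quintiles, it was 8.10 for RNA genes and 3.1 for coordinate-named features. Without the class of p listed as 0, or its quintile, these were 10.2, 22.0 and 3.71 with lower bounds above 1. The intervals behind this and the list length tests take features as independent. They are likely too narrow, as 14 of the 28 RNA genes with both peaks lay in 1 array. Reads shared between near-identical RNA genes stay open. The odds ratio of 2.24 for coordinate-named features was first taken to exclude this cause. It was 1.20 (0.603 to 2.41) with the D493A list shortened by p. The 18.4 (2.45 to 138) with the list shortened by fold cannot decide, for the reason given above. Shared reads therefore cannot be told apart from a preference of the active enzyme, and other causes were not tested. Within the PNPase list, median folds were lower for RNA genes (8.14) and coordinate-named features (5.045) than for coding sequences (12.6). Listed folds depend on the limit for a peak, since 9.69 was the lowest fold among PNPase peaks whose p matched 1 input read. These medians therefore cannot compare enrichment between the classes.

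The D493A list was longer, and folds under 30 lay mostly on steps in each list. Only 575 of 3880 D493A peaks had such folds, against 785 of 830 PNPase peaks, and higher folds were not examined for steps. These steps may come from dividing by very few input reads. Of the peaks on their list's step, 385 of 464 D493A peaks (83.0%) and 436 of 648 PNPase peaks (67.3%) carried the p of a binomial test against 1 input read. A laxer limit for D493A peaks is argued against by asking 10 step units of each D493A peak, the fewest of PNPase peaks matched to 1 input read. This left 3532 D493A peaks, 4.26 times the PNPase list, which was not cut. A step unit was taken as 1 read, which holds only where the input is 1 read. Thinner sampling of the same RNA in the PNPase library was first tested by D493A fold, where the top quintile had a PNPase peak 3.09 times as often as the bottom quintile, short of the 10 times set for it, and this decided nothing. Ranking by p instead, tried only after that outcome, gave a ratio of 67.2, but this ranking was picked knowing the gradient and is no test of it. With depth unknown and 1 PNPase sample, thinner sampling cannot be told apart from longer retention of RNA by the inactive enzyme.

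PNPase peaks covering part of a gene reached the 5' end more often than the 3' end. Direction along the contig as the whole cause cannot be told apart, since the ratio balanced over the strands was 1.37 (1.11 to 1.69) but reached 1 with the D493A list shortened by fold, at 1.15 (0.846 to 1.56). It stayed above 1 in the other settings run, from 1.29 (lower bound 1.002) with the list shortened by p to 1.48 (1.07 to 2.04) in the upper part of each list. Direction may be a part, since right ends were reached 1.77 times (1.44 to 2.18) as often as left ends in the balance of both strands, with 101 against 78 on the plus strand and 153 against 63 on the minus strand. No biological explanation was tested.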

How the results depend on the processing

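Leaving out contig 11, shortening the D493A list by p, splitting by strand, and the fold split, contig 11 and window results with all their alternatives were chosen after seeing the data. Of 56 alternative values, 39 were the same (31 in direction and side of the threshold, 8 values or counts without a test), 5 lost the call, 9 moved and 3 turned direction. Each value was counted once, so those that turned direction are not among the lost calls, even where their call was also lost. Peak overlap (35.3 to 100%), shared genes (odds ratios 1.92 to 111) and the untranslated share (odds ratios 2.03 to 14.1) kept theirs under every alternative run. The values for shared genes all rest on genes presumed from the tag numbering. For the untranslated share, the settings by fold add no support, because D493A folds of these features were lower than those of coding sequences. With strand ignored, rotated lists overlapped by 96.6%. In the settings by strand, rotation understates the overlap expected for peaks on genes. The 5' share was 43.6% on the plus strand and 54.1% with the D493A list shortened by fold, where the midpoint was 0.457, and both calls were lost. The midpoint was 0.469 in genes over 2 times the median peak width, where its call was lost with fewer peaks tested, and the 3' end of the peak lay at 0.868 by construction. The log2 fold difference lost its call in the upper part of each list (0.11) and with the list shortened by fold (-0.0073), and was -0.43 by p. Both rankings select on the fold itself or on a value tied to it. The contig 11 share lost its call, at 45.8%, with the list shortened by fold, where few features remained. Median D493A width and fold were 868.5 bp and 176 in the upper part, 915 bp and 296 shortened by fold, and 757.5 bp and 176.5 by p. PNPase medians in the upper part were 546 bp and 17.4. The cause of the other changes was not tested. No paired analysis was possible because the groups share fewer than 2 replicate numbers and the lists do not keep samples apart, so no replicate was left out. The tests of the 16 gene lists, and for shared genes the 50% overlap and strand settings, were not run. Depth is unknown and limits every comparison of list length.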

Other observations

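All tests in this part were chosen after seeing the data.

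Genes with a PNPase peak stood next to each other more often than shuffling gave. Of 1276 pairs of neighbouring features on 1 strand at most 50 bp apart, 156 had a PNPase peak on both, against a shuffle mean of 50.5 and a shuffle maximum of 76 (permutation p = 0.001, the smallest possible). Where a feature had a PNPase peak, its neighbour had one in 57.6% of cases, against 773 of 3868 features in all. The shuffles spread the calls over all D493A features, whatever their D493A p. They cannot separate this excess from runs of features with small D493A p, or from neighbours that lie on 1 transcript. In windows of 25 features, 4 regions exceeded the shuffle limit of 14, the 95th percentile of the highest shuffled windows. Besides the one on contig 11, they were contig 13 from 318943 to 341644 with 19 of 30 features, contig 15 from 441529 to 470819 with 19 of 33, and contig 16 from 6 to 10076 with 15 of 21, of which 14 were untranslated. Only contig 11, with 23 in its highest window, lay above the shuffle maximum of 16. The highest windows on contigs 13, 15 and 16 held 16, 16 and 15, which shuffling also reached. Windows of 15 and 40 also gave 4 regions each, not all at the same places.

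By width, the shares of D493A features with a PNPase peak were 24.9% in the narrowest quintile and 24.9% in the widest, with 16.8%, 16.3% and 16.9% between. Peak names in the PNPase list were numbered up to 4037, so 3207 numbers were not listed, and in the D493A list up to 4206, with 326 not listed. The commonest D493A fold was 13.3, at 75 peaks, and the commonest PNPase fold was 9.69, at 106 peaks. Among the 575 D493A peaks with a fold under 30, 80.7% lay on multiples of 2.22 (4.27% expected by chance). Among the 785 such PNPase peaks, 82.5% lay on multiples of 0.969 (6.92% by chance).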
